A study of Oryctolagus cuniculus with 16 samples.

How the data were processed

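Total RNA from fetal placentas at day 14 and polyA RNA from 6-day embryos was labelled with Cy3 and hybridised to Agilent rabbit arrays with 1 colour, per the labels' protocols. Vitrification used dimethyl sulfoxide and ethylene glycol in 2 steps at 20 °C, of 12.5% each for 2 min and then 20% each for 30 s, before plunging into liquid nitrogen. The 16 arrays fell into 4 groups of 4 by the treatment and tissue in the labels: control and vitrified placenta, and control and vitrified embryo. Placenta and embryo lay on separate slides, each scanned on its own, so that slide and tissue cannot be told apart and slide could not enter a comparison within a tissue.

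Each array's scanner file held the intensity of every spot, as written by Feature Extraction 10.7.3.1 with spatial detrending as background and multiplicative detrending, per the file headers. The deposited series table held log2 values. Its scale was found from the values: each column was the log2 of the raw median signal with its median moved to 0.0, with r from 0.99987 to 1.00 against the scanner file of the same array for 14 columns. The columns of placenta control 3 and vitrified 3 had r of 0.978 with their own scanner files and 1.00 with each other's. Which source carries the right labels is unknown, and the scanner files were used under the samples they are recorded for. How the table was centred beyond this, and any other processing, is not given in the sources used here. Probe positions are on build oryCun2, per the file headers.

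Each array had 61657 spots that were not controls, for 40884 probes. Spots of a probe were averaged, outlier flags were left out, and 140 probes with such flags on all their spots on some array were not used. No spot was saturated. Gene names came from the files' accessions (11429 probes), gene numbers (8161), symbols (428) and Ensembl transcripts shared with a named probe (340), the accessions and numbers through a RefSeq table of assembly mOryCun1.1 used for names only. In all 20358 probes had 1 symbol, 29 several and 20497 none, for 9362 symbols, of which 380 were only LOC numbers. Probes with several symbols were named by none. For 4214 genes with several probes the brightest stood for the gene in lists, and each probe was tested on its own in counts. Whether a probe lies in an exon or an untranslated region was not examined.

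Values were log2 of the processed signal minus each array's 75th percentile. Replicate arrays correlated with r from 0.940 to 0.985 in placenta controls, 0.967 to 0.986 in vitrified placentas, 0.856 to 0.967 in embryo controls and 0.896 to 0.985 in vitrified embryos, and no pair was identical. The design, tests, gene lists, rule for named genes and listed alternatives were fixed before the data were examined. Vitrified was compared with control in each tissue, control placenta with control embryo, and the vitrification effect in placenta with that in embryo. Each comparison used limma (lmFit and eBayes) on the arrays of its groups. Probes had to be well above background on at least 4 of the 8 arrays, in both tissues for the comparison of effects. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Differences are vitrified minus control or placenta minus embryo.

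Genes named in each tissue were the 12 with the largest rise and the 12 with the largest fall among probes that passed, had 1 symbol and had all 4 vitrified arrays beyond the 4 controls. Where fewer than 10 passed, the genes with the smallest unadjusted p were added up to 10, as values. From each list the members that passed were named, or else 2 with the largest change. Between tissues the rule took the 12 highest, the 12 lowest and 2 to 4 per list, and for the difference of effects the 5 with the smallest p. Other genes in the closing observations were chosen after their values were seen.

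The 24 gene lists were trophoblast identity, pluripotency and epiblast, endoderm and yolk sac, imprinted genes, steroid hormone synthesis, cholesterol synthesis, angiogenic signalling, endothelial cell markers, erythroid cell markers, leukocyte markers, maternal decidua and endometrium markers, and fetal mesenchyme and extracellular matrix. The others were matrix proteases and inhibitors, complement and coagulation, nutrient transport, glycolysis and hypoxia response, oxidative phosphorylation, heat shock and protein folding, antioxidant defence, apoptosis and p53 response, cell proliferation, DNA methylation and chromatin enzymes, interferon response, and cell junctions and epithelial cytoskeleton. No gene was in more than 1 list. The imprinted list holds ZRSR2, an X-linked gene not known as imprinted, and was kept as fixed. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as an alternative. The fry test asks only whether the genes of a list move one way on balance.

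The fits were tested on simulated data with the spread of the real arrays, with 50 probes changed by each of 1, 2, 3 and 4 on the log2 scale. In placenta 36%, 84%, 98% and 98% of them were recovered with 12 false calls, and in embryo 0%, 20%, 70% and 84% with 3. Between tissues 2%, 30%, 66% and 84% were recovered with 5 false calls, and for the difference of effects 2%, 36%, 68% and 88% with 10. A cell proliferation list shifted by 1 was found in each of the 3 comparisons with lists, with no other list called. The noise was drawn independently for each probe, so the simulated data held no correlation between genes. They therefore do not show how often the fits or the list test call falsely where genes are correlated.

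Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter, a filter for probes above background on all arrays, the series table, eBayes with trend and robust, array weights, the replicate number as a block, all 16 arrays in 1 fit, a 2-fold threshold, 1 probe per gene, the mean of a gene's probes, and leaving out each array. Added after seeing the data were a percentile over probes above background on all 16 arrays, the scanner files or table columns of the arrays numbered 3 in placenta exchanged, leaving both out, the row of the slide as a block, and array brightness as a covariate in embryo. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.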

Results

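Gene expression was measured in rabbit (Oryctolagus cuniculus) embryos and fetal placentas on 16 Agilent arrays with 1 colour (Cy3). The question named in the series' design is how vitrification, which freezes embryos to a glass in concentrated cryoprotectant, alters the transcriptome of the late blastocyst and of the fetal placenta. The 4 groups were fetal placenta at day 14 of gestation from transferred control or vitrified embryos, and 6-day embryos that were control or vitrified, with 4 arrays each. The series describes the 4 replicates of each group as independent but names no animals or litters, so p-values measure the spread between these samples, part of which may be technical. Placenta arrays received 200 ng of total RNA and embryo arrays 5 ng of polyA RNA. All placenta arrays lay on slide 1 and all embryo arrays on slide 2, so that tissue cannot be told apart from slide, RNA kind or RNA input. The 75th percentile of the signal ran from 116.5 to 309.2 on the placenta arrays and from 189.0 to 1246 on 7 embryo arrays, with 5108 on embryo control 3. Between 45.1% and 74.6% of spots were well above background, and the number of arrays limits the precision. Errors on log2 differences are standard errors with n = 4 arrays per group, adjusted p-values are Benjamini-Hochberg values from limma, and positions are on rabbit build oryCun2 as in the files. Where a probe was not well above background on any array of a group, its fold is a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

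The largest rises in fetal placentas from vitrified embryos, against control placentas, included genes of serum protein and lipid carriers, which were not tested as a group. Transthyretin (TTR, chromosome 9, 72863304 to 72863363), a carrier of thyroid hormone and of the retinol-binding protein, rose by 11.05 ± 0.43 on the log2 scale, and was above background on 1 of the 4 control arrays. Alpha-fetoprotein (AFP, chromosome 15, 76641622 to 76642330), a serum protein of the fetus, rose by 10.64 ± 0.97 and was measured on 3 control arrays. The liver-type fatty acid binding protein FABP1 (chromosome 2, 99432143 to 99434100) rose by 10.59 ± 0.62, with 1 control array above background. The high-density lipoprotein component APOA2 (chromosome 13, 31761814 to 31761873) was at least 876-fold higher, and no control array measured it. The adjusted p-values of these 4 genes in limma were 1.25e-06, 2.66e-04, 1.35e-05 and 1.25e-06.

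The other 8 genes of the 12 largest rises encode transporters, enzymes, a receptor and carriers of lipids or retinol. The retinol carrier RBP4 rose by 7.87 ± 0.55 and the organic anion transporter SLC22A8 by 7.49 ± 0.45, both with 3 of 4 control arrays above background. The remaining 6 were above background on no control array. An aldo-keto reductase (LOC100352971) was at least 257-fold higher and a glutathione S-transferase (LOC100328911) at least 199-fold. The endocytic receptor LRP2 was at least 114-fold higher, hepatic lipase LIPC 106-fold, the urea cycle enzyme OTC 65.1-fold and the lipoprotein component APOA1 54.8-fold, each as a lower bound. The bound of APOA1 fell to 27.4-fold without vitrified 2, where it was 4.77 against 0.42 to 1.15 on the other 3 arrays. The fitted change of APOA1 went from 6.95 to 3.41 with normexp background correction (limma adjusted p = 0.0685) and to 4.05 in the series table with the number 3 columns exchanged back (limma adjusted p = 0.0596), and no longer passed in either. In total 281 of 22341 probes tested (1.26%) rose and 0 fell at an adjusted p under 0.05 in limma, with 1070 higher and 599 lower at an unadjusted p under 0.05. The 281 comprised 201 probes of 96 named genes and 80 probes without a name, and 280 changed at least 2-fold. On all 281 probes the 4 vitrified arrays lay above the 4 control arrays. Unchanged probes do so in 1.43% of cases by chance, but these were selected by the test for such a difference, so the shares are not comparable. Of these probes, 130 were above background on no control array and 73 on every one.

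Among the fixed lists, endoderm and yolk sac genes rose together. Of 12 measured members 8 rose over all probes tested and 10 when adjusted over the list alone, with a median of 6.17 (5.76 with the 2 members that have only a bound set at it; camera adjusted p = 2.28e-26; adjusted p = 0.0652 with an estimated correlation). Besides TTR, AFP, APOA2, RBP4 and APOA1 these were the lipoprotein component APOB (6.58 ± 0.44), transferrin TF (5.75 ± 0.42) and fibrinogen chain FGG (3.78 ± 0.55). The limma adjusted p of FGG became 0.0602 without vitrified 1 and 0.0921 without both arrays numbered 3. Fetuin AHSG (0.02 ± 0.19) and the endoderm transcription factor GATA4 (-0.26 ± 0.43) did not pass. The means of the list on the control arrays were -1.76, -1.14, -1.60 and -2.53, and on the vitrified arrays 3.82, 5.09, 3.73 and 3.40. The medians of the 7 other cell type lists lay between -0.29 and 0.27.

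**Figure D1:**
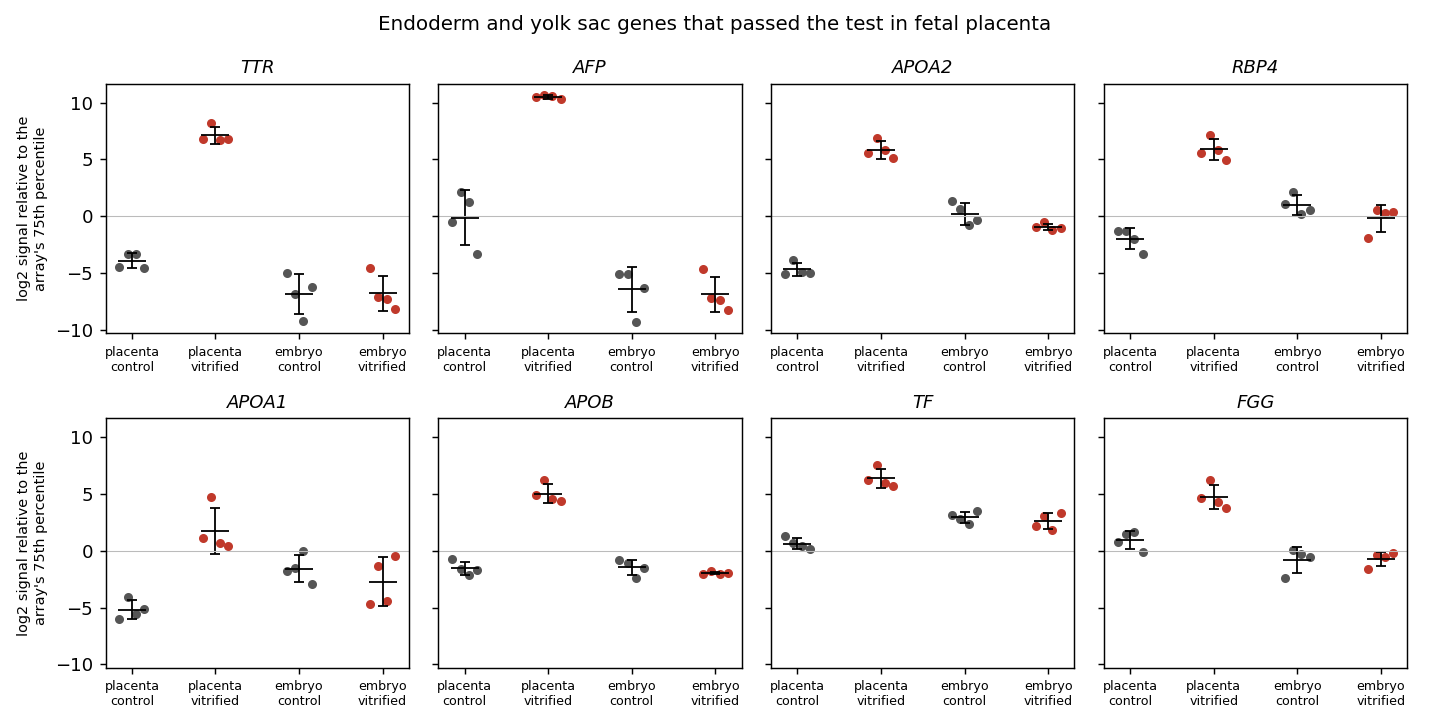
Log2 signal relative to each array's 75th percentile for the 8 endoderm and yolk sac genes that passed the test in fetal placenta, in the 4 groups. Points are arrays, horizontal marks are means and bars are SD (n = 4 arrays); for TTR the vitrified placenta arrays averaged 7.13 and the control placenta arrays -3.92.

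The complement and coagulation list shifted upward in the same vitrified placentas in which the endoderm list rose. Of 11 measured members 4 rose over all probes and 6 adjusted over the list alone, and 4 had negative differences (median 0.91; camera adjusted p = 1.62e-04; adjusted p = 0.118 with an estimated correlation). Coagulation factor F10 was at least 48.3-fold higher and antithrombin SERPINC1 at least 3.92-fold. The complement protease CFI rose by 3.20 ± 0.40 and prothrombin F2 by 2.01 ± 0.33, while the coagulation inhibitor TFPI (-0.48 ± 0.26) and CFH (-0.46 ± 0.43) did not pass. The list's camera adjusted p became 0.537 without vitrified 1, 0.287 without vitrified 3 and 0.219 without both arrays numbered 3. In these fits the probes of F10 and SERPINC1, above background on no control array, could not be tested, so the list was not the same. The limma adjusted p of F2 became 0.0589 without control 3, 0.104 without vitrified 1 and 0.0851 without vitrified 3, and those of CFI and F2 0.0921 and 0.286 without both arrays numbered 3. The fitted change of SERPINC1 went from 3.18 to 0.56 with normexp (limma adjusted p = 0.691) and to 0.93 in the table exchanged back (limma adjusted p = 0.263). In the same arrays, all 6 measured cholesterol synthesis genes had positive differences (median 0.71; camera adjusted p = 3.88e-04; adjusted p = 0.472 with an estimated correlation). None passed over all probes and 5 passed adjusted over the list alone, among them SQLE (1.11 ± 0.40) and HMGCR (0.63 ± 0.20), the rate-limiting enzyme. The brightest probe of MSMO1 gave 1.33 ± 0.34 and did not pass, while another of its probes did (1.44 ± 0.25). Of 24 cell proliferation genes 0 passed either way and 21 had positive differences, such as MCM5 (0.82 ± 0.79) and MCM7 (0.51 ± 0.47). Their median was 0.33 (camera adjusted p = 0.010, and 0.794 with an estimated correlation). The camera adjusted p was 0.0568 without control 4 and 0.0501 without both arrays numbered 3. In the fry test the adjusted p was 2.10e-04 for the endoderm list and 0.00537 for complement and coagulation. It was 0.107 for cholesterol synthesis and 0.411 for cell proliferation.

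Single members rose, in the vitrified placentas in which the endoderm list rose, from lists whose own test did not pass. Among 9 steroid hormone genes the estrogen sulfotransferase SULT1E1 was at least 76.8-fold higher. Among 18 nutrient transport genes the fatty acid transporter SLC27A2 rose by 4.49 ± 0.74, with 2 of 4 control arrays above background, and the heart-type fatty acid binding protein FABP3 by 1.75 ± 0.26. The limma adjusted p of SLC27A2 became 0.0990, 0.0903 and 0.0998 without vitrified 1, 2 and 3, and that of FABP3 0.0585 and 0.0724 without vitrified 1 and 3. Without both arrays numbered 3 they were 0.107 and 0.119. The steroid list had a median of -0.01 and a mean of 0.67, and the nutrient list a median of -0.07 and a mean of 0.19 with a downward camera direction, so that signs differed within each list (camera adjusted p = 0.904 and 0.976). Both counts were the same adjusted over the list alone. Of the 5 interferon response genes 0 passed over all probes and 1 adjusted over the list alone, USP18 (1.24 ± 0.32). The median of that list was 0.17 (camera adjusted p = 0.227).

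No member passed, over all probes or adjusted over the list alone, in the other 17 lists. These were trophoblast identity (8 measured members, median 0.12), pluripotency and epiblast (2 members, too few for the list test), imprinted genes (9, -0.07), angiogenic signalling (11, -0.18) and endothelial cell markers (5, -0.29). They also included erythroid cell markers (7, 0.27), leukocyte markers (8, 0.04), maternal decidua and endometrium markers (5, -0.04), fetal mesenchyme and extracellular matrix (13, 0.04), and matrix proteases and inhibitors (13, -0.09). The others were glycolysis and hypoxia response (13, -0.04), oxidative phosphorylation (22, -0.03), heat shock and protein folding (15, -0.06), antioxidant defence (12, 0.01), apoptosis and p53 response (8, -0.04), DNA methylation and chromatin enzymes (10, -0.03), and cell junctions and epithelial cytoskeleton (26, -0.03). Their camera adjusted p-values lay between 0.870 and 0.971, and the mean or the test had the opposite sign to the median for oxidative phosphorylation, DNA methylation enzymes and cell junctions. Differences among their members included those of the tight junction gene OCLN (0.91 ± 0.24), the heparanase gene HPSE (-0.86 ± 0.27, with its other probe at 0.58), the receptor FLT1 (-0.74 ± 0.29), the trophoblast gene GCM1 (-0.55 ± 0.38) and the erythroid spectrin SPTA1 (1.17 ± 0.41).

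**Figure D2:**
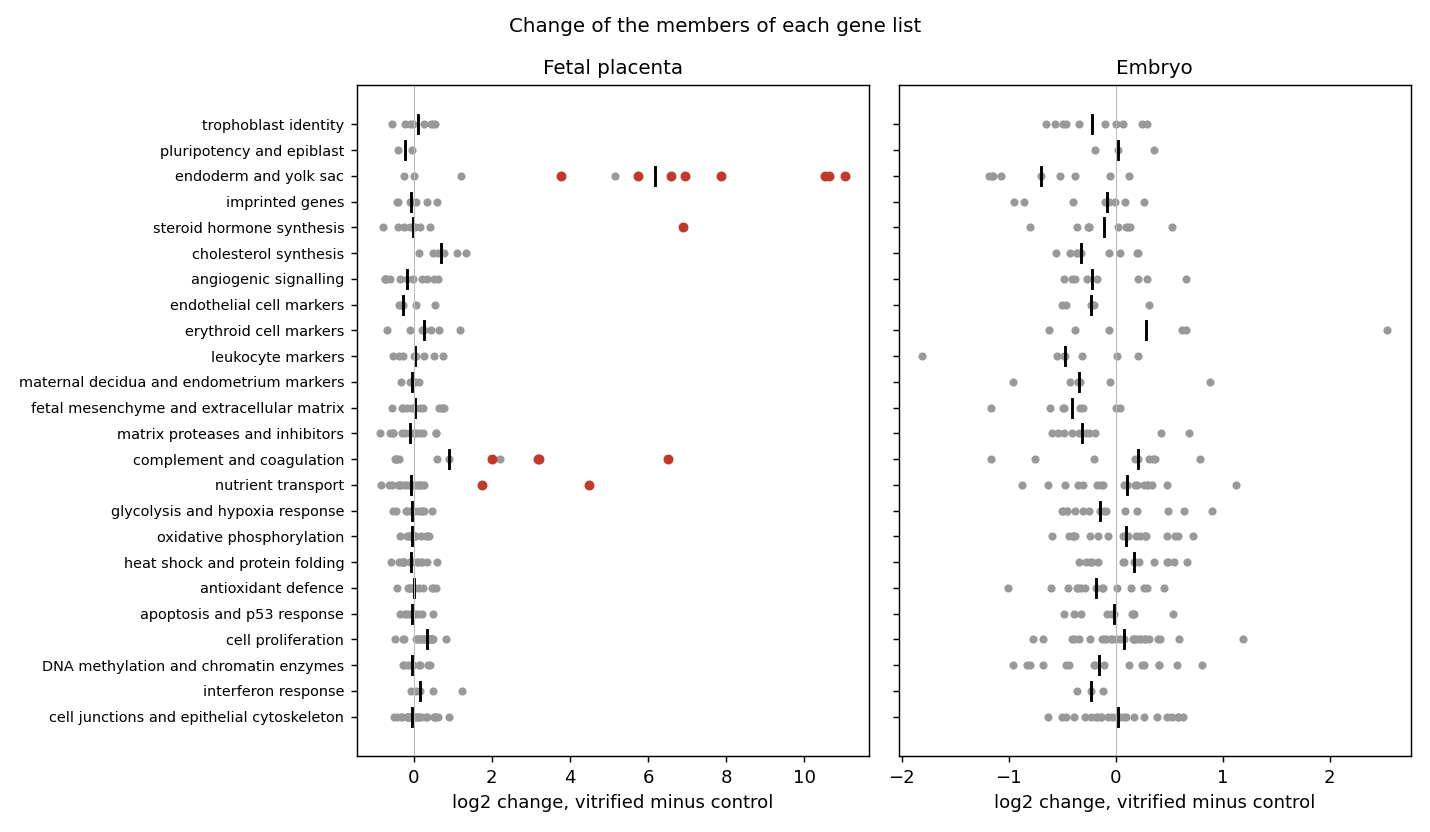
Log2 change, vitrified minus control, of each measured member of the 24 gene lists in fetal placenta (left) and embryo (right). Red points passed at an adjusted p under 0.05, grey points did not, and black marks are list medians; in placenta the endoderm and yolk sac list has its median at 6.17, and in embryo no member of any list passed.

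The placenta result rested on the labels of control 3 and vitrified 3. In the deposited series table those 2 columns match each other's scanner files, and with the table's labels 0 probes passed in limma, whether from the table (387 at an unadjusted p under 0.05) or from the scanner files (595 at an unadjusted p under 0.05). All 22 named genes that passed lost their calls there, and without both arrays 41 probes passed in limma. With the scanner files exchanged the endoderm list passed with the preset correlation (camera adjusted p = 4.65e-06) and not with an estimated one (adjusted p = 0.861 with an estimated correlation). The complement and cell proliferation lists passed with neither there (camera adjusted p = 0.231 and 0.537 with the preset correlation). The count was 68, 105, 75 and 134 without vitrified 1, 2, 3 and 4. Where a vitrified array was left out, 4 arrays above background were still needed. The 130 changed probes above background on no control array could therefore not be tested there. The count was 170 with normexp, 64 over probes above background on all arrays, 81 with 1 probe per gene (against 96 named genes), and 633 (543 higher, 90 lower) with array weights. Placenta control 1, 3 and 4 and vitrified 4 lay in row 1 of the slide, and control 2 and vitrified 1, 2 and 3 in row 2. Row and treatment therefore partly went together in placenta. With the row of the slide as a block 183 passed, and SERPINC1, F2, SLC27A2, FABP3 and the cell proliferation list (camera adjusted p = 0.444) did not. The changes of these genes were then 3.09, 1.78, 3.63 and 1.55 (limma adjusted p = 0.0513, 0.104, 0.0599 and 0.0643).

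In 6-day embryos no gene could be told apart between vitrified and control arrays. The smallest unadjusted p-values among named genes belonged to the vesicle transport GTPase RAB13 (-1.90 ± 0.54), the autophagy gene GABARAPL1 (-1.22 ± 0.36), the tight junction gene CLDN8 (1.93 ± 0.57) and the meiosis gene TEX12 (1.08 ± 0.35). They were followed by the arrestin ARRB1 (-1.36 ± 0.47), CLEC16A (-1.23 ± 0.44), PPFIBP2 (1.54 ± 0.56), the macrophage gene MPEG1 (-1.81 ± 0.67), the replication gene GINS3 (-1.10 ± 0.40) and myostatin MSTN (-1.29 ± 0.48). None passed: 0 of 25631 probes did in limma, with 186 (0.726%) at an unadjusted p under 0.05, 86 of them higher. That share lay below 0.05, the share that chance alone gives on average. The dimmest arrays (control 1, 2 and 4 and vitrified 1) set against the others gave 7346 such probes, with 0 passing. With array brightness as a covariate the labelled groups gave 802, and without single arrays from 57 to 677, with 0 passing in each. The 0 is therefore not read here as a sign of little effect. In simulated data with the spread of these arrays and independent noise, 0% of changes of 1, 20% of 2, 70% of 3 and 84% of 4 on the log2 scale were recovered.

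The endoderm and yolk sac list shifted downward in vitrified embryos with the preset correlation. Of 9 measured members 8 had negative differences and 0 passed, over all probes or adjusted over the list alone, with APOA2 at -1.16 ± 0.48 and RBP4 at -1.19 ± 0.62. The list's median was -0.69 (camera adjusted p = 0.0133; adjusted p = 0.803 with an estimated correlation; fry adjusted p = 0.878). Its adjusted p became 0.224 without control 2, 0.0962 without control 4, 0.103 without vitrified 1, 0.273 without vitrified 3 and 0.329 with no filter on dim probes. No member of the other 23 lists passed, over all probes or adjusted over the list alone, and their camera adjusted p-values were 0.312 or more. Differences among their members included those of the fatty acid transporter CD36 (1.12 ± 0.54), the mitotic kinesin CENPE (1.19 ± 0.46), the glutathione S-transferase GSTP1 (-1.01 ± 0.51), the imprinted gene NNAT (-0.86 ± 0.34) and ZRSR2 (-0.95 ± 0.49), a splicing factor gene on chromosome X that the imprinted list holds but that is not known as imprinted. Angiogenic signalling (median -0.22), glycolysis and hypoxia response (-0.15) and apoptosis and p53 response (-0.02) had an upward camera direction against a negative median and mean. Uteroglobin SCGB1A1, a secretory protein of the uterus and a member of the decidua list, ran from -4.54 to 1.17 across the 8 arrays. Beta globin HBB2, of the erythroid list, ran from -4.93 to 4.45. Both were highest on the same 3 arrays, control 4, vitrified 3 and vitrified 4. The group differences were 0.88 ± 1.23 for SCGB1A1 and 2.54 ± 1.72 for HBB2.

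**Figure D3:**
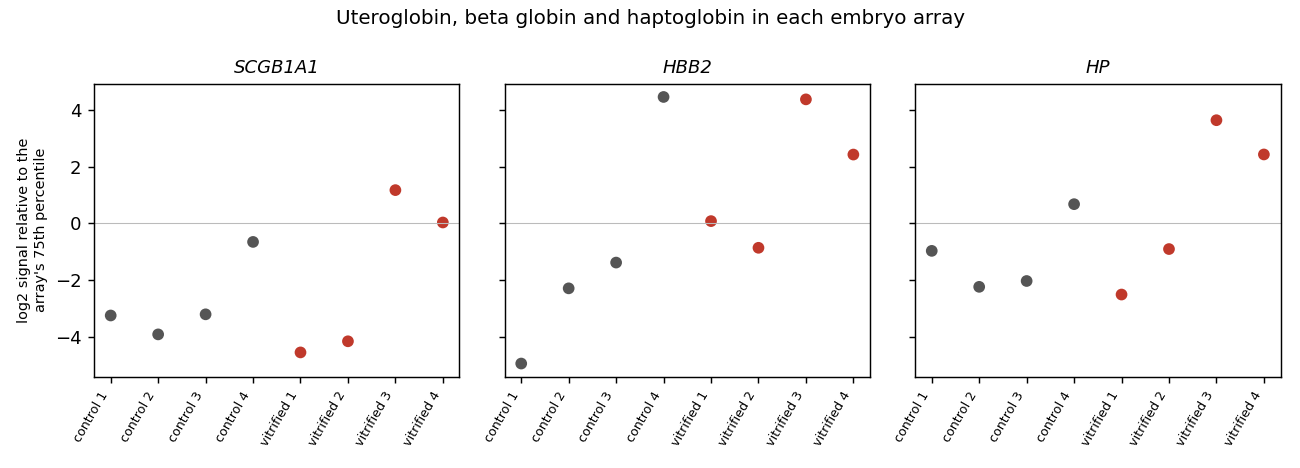
Log2 signal relative to each array's 75th percentile for uteroglobin (SCGB1A1), beta globin (HBB2) and haptoglobin (HP, chosen after its values were seen) on each of the 8 embryo arrays, control in grey and vitrified in red. Each point is 1 array; the 3 highest arrays for all 3 genes are control 4, vitrified 3 and vitrified 4, and SCGB1A1 runs from -4.54 to 1.17.

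Control placenta and control embryo expressed different sets of genes, which gives the context of the vitrification comparisons. Higher in placenta were the matrix protein SVEP1 (10.79 ± 0.50), HBB2 (10.63 ± 1.47), the collagens COL3A1 (9.98 ± 0.42) and COL1A2 (8.10 ± 0.33), the interleukin receptor antagonist IL1RN (9.48 ± 0.34), EFHC1 (8.83 ± 0.44), periostin POSTN (8.13 ± 0.88) and embigin EMB (8.09 ± 0.41). EFHC1, POSTN and EMB were above background on 1 embryo array and HBB2 on 3. No embryo control array measured decorin DCN (at least 260-fold higher in placenta), IL20 (180-fold), FABP4 (140-fold) or ZMAT1 (125-fold). Higher in embryo were carboxypeptidase CPB1 (at least 599-fold), LRP2 (383-fold), carbonic anhydrase CA4 (319-fold), the growth factor GDF3 (302-fold), transglutaminase TGM3 (241-fold), the oocyte and embryo gene KHDC3L (238-fold), OTC (105-fold), STMN2 (70.4-fold) and TNNC1 (61.2-fold). All of these are lower bounds, since no placenta control array measured them. Without embryo control 3 the bounds of DCN, IL20, FABP4, ZMAT1 and TGM3 were 155-fold, 108-fold, 87.1-fold, 74.7-fold and 148-fold. That of FABP4 was also 88.7-fold without placenta control 1 and 212-fold without placenta control 4, and that of TNNC1 38.6-fold without embryo control 1. For regucalcin RGN (-8.04 ± 0.58), TMEM229B (-7.20 ± 0.60) and DDIT4L (-7.19 ± 0.54) the difference is placenta minus embryo, with DDIT4L above background on 1 placenta array.

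In total 9510 of 23546 probes (40.4%) differed in limma, 4967 (52.2%) of them higher in placenta, and 2619 named genes were among them. The share higher in placenta was 39.4% with median scaling and 23.5% in the deposited table. The median of all probes moved by -0.29 and -0.54 there, by 0.25 with normexp and by 0.17 with the percentile taken over probes above background on all 16 arrays. Over probes above background on all arrays 5804 passed.

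Of the lists, 11 passed between the tissues with the preset correlation, and 0 with an estimated correlation. The fry adjusted p-values of these 11 lay between 8.23e-05 and 0.0064. That test also passed lists that camera did not, such as nutrient transport (fry adjusted p = 0.0018). Matrix and mesenchyme genes were higher in placenta: 8 of 12 passed and 10 adjusted over the list alone (median 5.21; camera adjusted p = 3.51e-05; adjusted p = 0.158 with an estimated correlation). So were matrix proteases and inhibitors, with 9 of 13 higher and 1 lower either way (median 3.23; camera adjusted p = 1.27e-04; adjusted p = 0.123 with an estimated correlation), such as TIMP3 (7.71 ± 0.50) and the plasminogen activator PLAU (7.27 ± 0.51). Erythroid genes were higher for 6 of 7 members, 7 adjusted over the list alone (median 2.43; camera adjusted p = 0.00304; adjusted p = 0.123 with an estimated correlation), such as HEMGN (5.06 ± 0.66). Interferon response genes were higher for 3 of 4 either way (median 3.90; camera adjusted p = 0.00367; adjusted p = 0.123 with an estimated correlation), such as IFIH1 (5.27 ± 0.45). Angiogenic signalling genes were higher for 7 of 11, 8 adjusted over the list alone (median 2.68; camera adjusted p = 0.00367; adjusted p = 0.428 with an estimated correlation), with the hypoxia factor EPAS1 at least 63.2-fold and FLT1 at least 10.6-fold higher (37.7-fold and 6.34-fold without embryo control 3). Its camera adjusted p was 0.367, 0.297, 0.121 and 0.107 without placenta control 1, 2, 3 and 4. In these fits the probes of EPAS1 and FLT1, above background on no embryo control array, could not be tested. The list was therefore not the same, and these values do not show that single arrays carried it.

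Of 9 members of the imprinted list 5 were higher and 1, ZRSR2 (-1.34 ± 0.48), lower, and 6 and 1 adjusted over the list alone (median 1.39; camera adjusted p = 0.0221; adjusted p = 0.123 with an estimated correlation), such as SGCE (4.85 ± 0.56) and GNAS (3.68 ± 0.46). Complement and coagulation genes were higher for 6 of 8 either way (median 1.93; camera adjusted p = 0.0221; adjusted p = 0.123 with an estimated correlation), such as TFPI (3.53 ± 0.65). That list's camera adjusted p was 0.0666, 0.0534 and 0.0578 without placenta control 1, 2 and 3. Of its 8 members 1, CFH, had only a bound, and its probe could not be tested in these fits. Cell proliferation genes were higher in embryo for 16 of 26 members and lower for 1, the kinesin KIF20A (6.10 ± 0.44), with 19 and 1 adjusted over the list alone. Their median was -1.27 (camera adjusted p = 5.08e-05; adjusted p = 0.123 with an estimated correlation), and CDC20 stood at -3.41 ± 0.43. Oxidative phosphorylation genes were higher in embryo for 9 of 22, 10 adjusted over the list alone (median -1.04; camera adjusted p = 0.00138; adjusted p = 0.428 with an estimated correlation), such as NDUFA9 (-2.79 ± 0.33). So were cholesterol synthesis genes, 6 of 9 and 9 adjusted over the list alone (median -1.54; camera adjusted p = 0.00158; adjusted p = 0.123 with an estimated correlation), such as SQLE (-1.83 ± 0.47). All 3 pluripotency genes were higher in embryo either way (median -2.82; camera adjusted p = 0.0287; adjusted p = 0.238 with an estimated correlation), namely DPPA5 (-2.34 ± 0.33), DNMT3B (-4.19 ± 0.89) and OTX2 (-2.82 ± 0.78, above background on 1 placenta and 3 embryo arrays). OTX2 stood at -0.36 with normexp (limma adjusted p = 0.384) and at -2.26 with array weights (limma adjusted p = 0.0653), so its call ended in both. That list's adjusted p was 0.0596 without placenta control 1 and 0.0528 with median scaling.

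The other 13 lists had members on both sides or a test that did not pass. Differences that passed in them included those of the sphingosine receptor S1PR1 (7.53 ± 0.58), the aromatase CYP19A1 (4.38 ± 0.68) and the integrin ITGB4 (4.72 ± 0.54) on the placenta side, with FABP3 (-6.65 ± 0.38) and GSTP1 (-3.47 ± 0.41) on the embryo side. GCM1 was at least 10.72-fold higher in placenta (6.396-fold without embryo control 3) and the calcium-binding protein CALB1 at least 35.6-fold higher in embryo. Of 11 endoderm and yolk sac genes 4 were higher in placenta and 4 in embryo, the same adjusted over the list alone, and of 20 nutrient transport genes 7 and 6 (7 and 7 adjusted over the list alone). The camera adjusted p-values of the 13 lists lay between 0.0943 and 0.924. For trophoblast identity (median -0.55, mean 0.10) and for decidua markers (median 0.09, mean -0.15) the signs differed.

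The vitrification effect differed between the tissues for 122 of 20875 probes, and the 5 named genes with the smallest p were APOA2, FABP1, LIPC, APOB and LRP2. The placenta effect minus the embryo effect was 12 ± 0.61 for APOA2 (limma adjusted p = 3.72e-09), whose own effects were 10.78 in placenta and -1.22 in embryo. It was 11.71 ± 0.69 for FABP1, 8.59 ± 0.54 for LIPC, 8.30 ± 0.58 for APOB and 7.30 ± 0.54 for LRP2, with embryo effects from -0.49 to -0.13. Each value is for the gene's probe with the smallest p. For APOA2, FABP1 and APOB it is another probe than the one given above for placenta, and the placenta effects of FABP1 and APOB were here 11.24 and 7.81. Those of APOA2, LIPC and LRP2 are fitted values, since no control placenta array was above background for them. All 122 had a more positive effect in placenta, 86 of them from 41 named genes, and 0 a more negative one in limma, with 549 and 250 at an unadjusted p under 0.05. Of the 122, 121 were also among the probes that rose in placenta. The count was 0 with the labels of the series table, 39 without both placenta arrays numbered 3, 58 with normexp, 12 over probes above background on all arrays, and 49, 50, 52 and 66 without placenta vitrified 1, 2, 3 and 4. Where a vitrified placenta array was left out, probes above background on no control placenta array could not be tested. Across the 20875 probes, which are not independent replicates, the effects in the tissues had a Pearson correlation of -0.117 and a Spearman correlation of -0.120.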

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

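The tests of yolk sac tissue, of a single RNA source, of a change in placental cells and of the splits for the count of placenta probes were chosen after the result was seen, while those of scaling and background correction and of the other splits were not.

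The vitrification effect differed between placenta and embryo for 122 probes. The placenta effect minus the embryo effect was 12 for APOA2, 11.71 for FABP1, 8.59 for LIPC, 8.30 for APOB and 7.30 for LRP2 on the log2 scale. Those of APOA2, LIPC and LRP2 are fitted values and no measure of size, since no control placenta array was above background for them. Of 100 drawn splits of the arrays within both tissues 4, the labelled one included, gave as many probes. That share is under 0.05, but 2 splits that kept neither tissue's labels gave 848, the highest, and 682, and 3 that kept the placenta labels and regrouped the embryo arrays gave 126, 120 and 116. The splits are therefore not read here as excluding chance. The counts of 848 and 682, so far above 122, point to a structure of the samples, and which one was not tested.

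The rise of probes in vitrified placentas, endoderm genes among them, was not the product of scaling or background correction alone. The lowest count of all changed probes under another such setting was 170 against 281. That setting was normexp, where 20 of the 22 named genes still passed and APOA1 and SERPINC1 did not. Median scaling and the other percentile move all probes of an array by 1 value, so they bear little on rises of this size. Under the scanner files' labels 1 of 35 splits, the labelled one, gave as many as 281, and the highest other gave 3. That is the smallest share 35 splits can give, and under the series table's labels the count was 0. At an unadjusted p under 0.05 in limma other splits gave up to 2691 probes, against 1669 for the labelled one. The splits are therefore not read here as excluding chance. A candidate explanation is yolk sac or other endoderm tissue in the vitrified samples. The list's median of 6.17, which restates the rise itself, stood against -0.29 to 0.27 for 7 other cell type lists. AFP and TTR had means of 10.52 and 7.13 on the vitrified arrays. A single RNA source with differing shares could give the 98.2% of changed probes on which vitrified 2 was highest, but so could any shared change that was larger in that sample, and the array was picked after it was seen. A change of expression in the placental cells cannot be told apart from these, since the median change of the probes (3.78) moves with the group either way. Above background on all 4 control placentas were 6 of 12 measured list members. These were TF, FGG and APOB, which passed over all probes, and GATA4, VTN and AHSG, which did not. Albumin ALB was above background on 3 vitrified and 0 control arrays.

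Single arrays stood far from the other 3 of their group in 9 of 120 groups of values tested (7.5%, with 5% by chance). TTR was 8.24 on placenta vitrified 2, with the others from 6.67 to 6.83. APOA1 was 4.77 there, with the others from 0.42 to 1.15, and SERPINC1 was -0.55, with the others from -2.78 to -2.42. APOA2 was -3.84 on placenta control 2, with the others from -5.06 to -4.89. TGM3 was -3.00 on placenta control 4, with the others from -5.95 to -5.61, and TNNC1 was -3.69 there, with the others from -5.56 to -5.25. No placenta control array was above background for APOA2, TGM3 or TNNC1, so their outliers lie among signals below background and do not show expression. Placenta control 4 was also the dimmest placenta array (75th percentile 116.5). PPFIBP2 was -4.49 on embryo vitrified 1, with the others from -3.31 to -3.11. OTC was 1.19 on embryo control 1, with the others from 3.03 to 3.28. The 75th percentile of the signal was 5108 on embryo control 3, with the other embryo controls from 274 to 442.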

How the results depend on the processing

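The tests with exchanged or left-out arrays numbered 3, the row of the slide, array brightness and the percentile over probes above background on all arrays were chosen after the data were seen. In placenta 281 probes changed. The count was 170 with normexp, 64 above background on all arrays, 0 in the series table, 633 with array weights, 81 with 1 probe per gene, 0 with scanner files exchanged, 187 in the table exchanged back, 41 without both number 3 arrays, 183 with the slide row as a block, and 68 to 269 without single arrays. With arrays left out, 4 arrays above background were still needed. Without a vitrified array, the 130 changed probes above background on no control array could therefore not be tested. The same holds for the difference of effects. The filter for all arrays also left such probes out, and 1 probe per gene covers named genes only, of which 96 had changed. The falls in these settings are thus partly set by which probes were tested. Other causes were not tested. Quantile normalization (250 of 253 shared), median scaling (280 of 318 shared) and the remaining settings stayed within 1.5 times. For the difference of effects, 122 became 58 with normexp, 12 above background on all arrays, 0 in the series table and with files exchanged, 76 in the table exchanged back, 39 without both number 3 arrays, and 49 to 128 without single arrays. Between tissues 9510 became 5804 above background on all arrays. Placenta lists fell from 4 to 2 in the series table, with files exchanged and without both number 3 arrays, and to 0 with an estimated correlation. The embryo list was lost (0) with no filter and with an estimated correlation, and 0 to 1 passed without single arrays. Tissue lists fell from 11 to 4 above background on all arrays, where only 7 of the 11 could be tested, and to 0 with an estimated correlation. The embryo probe count was 0 in every setting, and the correlation of effects ran from -0.162 to 0.0102. With normexp SREBF2 (0.055) and SIRT1 (0.38) turned to the placenta side. The replicate block gave 338 probes in placenta, 0 in embryo and 127 for the difference of effects, and the same number of lists. Controls matched best by their own number were 2 of 4 in placenta and 1 of 4 in embryo. So few arrays do not settle whether the numbers pair them. The slide as a block was not run, since each tissue lies on 1 slide. Dim signals limit the folds of probes below background, which are bounds.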

Other observations

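The tests of the exchanged arrays, uteroglobin, globin and brightness, and all genes named in the next paragraph, were chosen after the results were seen.

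The 96 named genes that rose in vitrified placentas also included the following, which were picked by hand and not tested as groups. Among them were protein C (PROC, at least 40.4-fold), factor F9 (at least 26.2-fold), the inter-alpha-trypsin inhibitor ITIH2 (at least 25.3-fold), the heme carrier HPX (4.76 ± 0.78, 1 of 4 control arrays above background) and the plasmin inhibitor SERPINF2 (2.78 ± 0.38). Others were the cation transporter SLC22A1 (at least 20.5-fold), the cystine transporter subunit SLC3A1 (at least 18.7-fold) and the bile salt pump ABCB11 (3.52 ± 0.37, 3 control arrays). The lipoprotein assembly gene MTTP (at least 8.36-fold), the elongase ELOVL2 (3.85 ± 0.43) and the acyl-CoA synthetase ACSL5 (2.71 ± 0.40) rose too. So did the double-stranded RNA sensor TLR3 (at least 11.7-fold), the transcriptional regulator CITED1 (3.79 ± 0.39), the fibroblast growth factor co-receptor KLB (2.87 ± 0.36) and the angiotensin receptor AGTR1 (1.68 ± 0.30). The smallest rise was that of the Wnt antagonist FRZB (0.93 ± 0.17).

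Part of this set was also expressed in 6-day embryos, but a smaller share than of all probes tested in placenta. Of the 281 probes, 202 were above background on at least 4 of the 8 embryo arrays and 38 on none. Of all 22341 probes tested in placenta, 20875 met that filter in embryo. RGN, LRP2, CA4 and CITED1 averaged 8.44, 4.83, 4.08 and 3.24 over the embryo arrays, while the brightest probes of TTR (-6.83) and AFP (-6.67) were above background on none. The other AFP probe was above background on 1 control embryo array. In embryos the vitrification difference of the 202 probes had a median of -0.20, with 6 at an unadjusted p under 0.05 in limma. Of all 25631 probes tested in embryo 186 had so small a p.

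Placenta control 3 and vitrified 3 are exchanged between the series table and the scanner files. With the table's labels 2 placenta arrays were out of place on the endoderm list, and with the scanner files' labels 0 were. On the placenta arrays not numbered 3 the list's means were -1.76, -1.14 and -2.53 for control and 3.82, 5.09 and 3.40 for vitrified. Under the scanner files' labels control 3 (-1.60) and vitrified 3 (3.73) lay with their own groups. Whether the scanner files or the columns of the table were exchanged still cannot be told apart. The comparison assumes that the group difference on the other arrays holds for those numbered 3. The count of changed probes was 281 under the labels of the scanner files and 0 under those of the table.

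The 3 embryo arrays highest for uteroglobin SCGB1A1 were control 4 (-0.65), vitrified 3 (1.17) and vitrified 4 (0.03), with the other 5 from -4.54 to -3.20. Brightness of the arrays does not account for this, since only 1 of the 3 was among the 3 brightest. The same 3 arrays were highest for beta globin HBB2 (4.45, 4.36 and 2.42). The exact one-sided p of that overlap, 0.0179, restates the observation that prompted the test and is evidence for no source. Of 3 more genes looked at, haptoglobin HP and serum amyloid A (LOC100009168) were highest on the same 3 arrays, and S100A8 was not. It was highest on vitrified 1 (-1.84), and the same 3 arrays came next: control 4 (-3.99), vitrified 4 (-4.13) and vitrified 3 (-4.13). S100A8 was above background on only 3 of the 8 embryo arrays. Whether maternal cells or uterine fluid were recovered with the embryos stays open, and no explanation from the biology of the embryos themselves was tested.

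Other splits of the 8 arrays of a comparison bear on the remaining results. For the 4 placenta lists 2 of 35 splits gave as many, with 4 as the highest other, and a chance split was not excluded. The embryo count of 0 is matched by any split, so that 35 of 35 (highest other 0) says nothing. The 1 embryo list was matched by 13 of 35 splits (highest other 2), and chance was not excluded. Between tissues, 9510 probes were given by 1 of 35 splits, with 1 probe as the highest other. Every other split put placenta and embryo arrays together in both groups, so low counts there were likely in advance. The splits do not tell tissue apart from slide or RNA kind. The 11 lists between tissues were matched by 2 of 35 splits, with 11 as the highest other, and chance was not excluded. The correlation of effects (-0.117) was matched by 51 of 100 drawn splits, with 0.516 as the farthest other from 0, so chance was not excluded.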
